A study of Arabidopsis thaliana with 3 samples.

How the data were processed

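RNA from Arabidopsis thaliana seed of ecotype Columbia was hybridised to 3 Affymetrix ATH1 arrays, 1 for unimbibed seed, 1 for seed imbibed for 3 days on untreated medium and 1 for seed imbibed for 3 days on medium with trichostatin A (TSA), an inhibitor of histone deacetylases. The labels give the TSA concentration in different units in different fields; 10 µM is the value stated for the treated sample itself. The deposited values are intensity values on a linear scale, a signal for each probe set, and were made with MAS5, per the submitters' processing notes. Its version, its scaling target and any detection calls are not given in the sources used here. All 3 columns were mapped to their samples by name, and 0 columns were left unmapped.

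The table held 22810 probe sets, of which 64 were AFFX controls and stayed out of all counts, leaving 22746. The 2% trimmed means of the deposited signals were 26.5 for unimbibed seed, 43.4 for untreated imbibed seed and 44.4 for TSA-treated seed, a range of 46.8% of their mean. By a rule fixed before the data were examined, arrays whose trimmed means differed by over 5% were scaled to a common trimmed mean, with factors of 1.44, 0.877 and 0.859. Such scaling sets the average signal equal, so a change of total messenger RNA per seed cannot be seen in the ratios. Scaled signals below the 40th percentile of all pooled values, a signal of 10.7, were raised to that floor before the log2 ratio was taken. A probe set was called higher or lower at a ratio of at least 2-fold, and "rose" or "fell" is written only of such a change. A ratio with a side at the floor is a bound and is given as "at least". With 1 array per group there was no test and no p-value, and the number of arrays limits the precision.

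Gene names came from the platform annotation held for these probe sets, updated by gene identifier through the RefSeq gene table of assembly TAIR10.1. It paired 13513 probe sets with 1 gene, 503 with several and 8730 with none, and 13436 of the 13513 matched the gene table while 77 kept their older name. These covered 13355 loci. A probe set paired with none is unnamed here, not without a gene. No genome build was stated for the arrays, so no coordinates are given.

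Before the data were examined, 25 gene lists were written down, with 427 entries, of which 103 had a probe set of their own. The other entries could not be measured, so their absence says nothing of their expression. A probe set of their own was held by 5 of 13 storage protein, 4 of 12 oil body and 3 of 16 seed maturation regulator entries. The same held for 8 of 46 nuclear photosynthesis and 8 of 32 histone entries. The value of a list is the median log2 ratio over its measured members, with 1 value per locus as the mean over its probe sets; a member was measured where at least 1 of its signals was above the floor. Where at least 5 members were measured, the median was placed among 10000 random lists of the same size matched on mean signal in 20 bins, which describes these arrays and is not a test across seeds. Of the 3 lists planned by rule, those for ribosomal proteins and transposable elements could not be built, because the tables used hold no gene descriptions, and the organelle list was built as the plastid-encoded genes. The named genes are the 10 highest and 10 lowest ratios among probe sets above the floor on both arrays, the 5 brightest calls in each direction whose other side was at the floor, and, in each list, the 2 members with the highest signal and the 2 with the largest TSA ratio in size. All measured seed maturation regulators are named as well, and the linker histone HIS1-3 was added after the values had been seen. A list of 118 cytosolic ribosomal protein loci, written from general knowledge, and the classes of plastid and mitochondrial genes were chosen after the values had been seen.

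Error was gauged from 18 hybridisation controls, whose log2 ratios had an SD of 0.17 for imbibed over unimbibed seed and 0.14 for TSA over untreated seed, and from loci with several probe sets, whose ratios differed with an SD of 0.76 over 42 loci and 0.38 over 49 loci. Neither includes the variation between batches of seed. The overlap of the calls was set beside 100 simulations with no TSA effect and a noise SD of 0.50 per array. This upper estimate was taken from the median absolute deviation of the TSA ratios of probe sets above the floor on both imbibed arrays. It was used for every probe set and array, dim ones included. The procedure was tested on simulated data made from the TSA comparison, with 22746 probe sets. Changes were placed only in probe sets with an untreated signal over 4 times the floor, so recovery of dimmer ones was not tested. The procedure called 25 of 50 probe sets changed 2-fold, and 50 of 50 at each of 4-fold, 8-fold and 16-fold. It also called 128 of 22546 unchanged ones (0.568%), with a noise SD of 0.38 in the ratio. That rate holds for this lower noise only: the simulations with an SD of 0.50 per array called 1120 probe sets higher and 1117 lower on average with no TSA effect. Of 200 unchanged lists, 9 lay outside the central 95% of random lists, and 20 of 20 lists shifted by 2-fold lay above it. Members of these lists had simulated untreated signals over 2 times the floor.

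The alternatives tried, all fixed in advance, were signals as deposited, scaling on the 75th percentile, quantile normalization, scaling on the hybridisation controls, floors at the 25th and 60th percentile, no floor with log2(signal + 1), a 4-fold threshold, the brightest probe set per locus, all list members, and leaving out probe sets that match several transcripts. Scaling on the poly-A controls, bacterial transcripts that are added before labelling, was chosen after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.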

Results

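Transcript levels were measured in Arabidopsis seed in 3 states: unimbibed, imbibed for 3 days, and imbibed for 3 days with 10 µM TSA. Each state was measured on 1 array, so there are no replicates and no difference has a replicate check. After scaling, 57.0% of probe sets were above the floor in unimbibed seed, 61.7% in untreated imbibed seed and 61.2% in TSA-treated seed. The 100 brightest probe sets held 29.3% of all signal in unimbibed seed, against 15.2% and 16.6% in imbibed seed without and with TSA. Signals of 3′ over 5′ probe sets, a sign of RNA integrity, were 1.82, 4.66 and 4.31 for actin on the unimbibed, untreated and TSA arrays, 1.31, 0.876 and 1.497 for GAPDH, and 3.87, 3.17 and 2.71 for ubiquitin. A second set of control probe sets gave 1.08, 1.096 and 1.43 for actin, 0.667, 0.913 and 0.757 for GAPDH, and 2.21, 2.02 and 2.12 for ubiquitin.

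Imbibed seed was compared with unimbibed seed to describe germination without the inhibitor. Most measured LEA, storage protein and oil body transcripts fell, and most measured photosynthesis and cell wall expansion transcripts rose. The LEA family (late embryogenesis abundant), which protects cells during drying, had a median log2 ratio of -6.31 over 29 measured members, of which 20 fell and 5 rose. The dehydrin AT2G21490 went from a signal of 8472 to 19.2, a log2 ratio of -8.78, and AT3G15670 from 10638 to 124.4, a log2 ratio of -6.42. M10, a further member, was at least 690-fold lower after imbibition. All 5 measured seed storage protein transcripts fell, with a median of -6.12, among them the vicilin-like PAP85 at -8.75 and AT2G28490, at least 405-fold lower. All 4 measured oil body protein transcripts fell, with a median of -6.34, including the oleosin AT3G01570 at -7.41 and AT2G25890 at -6.99.

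Of 6 measured small heat shock proteins, 5 fell, with a list median of -3.60. AT1G53540 had a log2 ratio of -4.37, AT1G52560 was at least 39.4-fold lower, ATHSP22.0 was at least 6.62-fold lower, and AT5G51440 had a log2 ratio of 0.05. The medians of the LEA, storage and small heat shock lists lay below those of all 10000 random lists. Only 3 of the 16 listed seed maturation regulators had a probe set of their own. Of these, EEL, a bZIP transcription factor, fell with a log2 ratio of -3.38 and BZIP53 had a log2 ratio of -0.67. BBM, at the floor after imbibition, was at least 1.11-fold lower.

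All 8 measured nuclear photosynthesis transcripts rose, with a median of 3.59, above all random lists. Rubisco activase, RCA, went from 11.6 to 485.3 (log2 ratio 5.38), LHCB4.2 rose by a log2 ratio of 2.70 and LHCB4.1 by 1.11, and PSAN was at least 9.46-fold higher. Of the chlorophyll biosynthesis list, PORB was at least 87.4-fold higher and CHLM had a log2 ratio of 3.29. In the cell wall expansion list 8 of 9 measured members rose, with a median of 3.44. XTH19 was at least 41.7-fold, XTH16 at least 21.9-fold and EXPA8 at least 5.18-fold higher, and EXPB1, at the floor after imbibition, was at least 1.38-fold lower. Among plastid-encoded genes 36 of 65 rose and 1 fell, with a median of 1.12; atpB rose by a log2 ratio of 1.70, the 1 that fell was psbC at -1.90, and clpP and petL had log2 ratios of -0.54 and -0.40.

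The core and linker histones had a median of 0.90, at the percentile 95.4 of random lists, with 3 of 8 higher and 1 lower. Those 8 were H2B and linker histone genes, and no H2A, H3 or H4 gene was measured. The linker histone AT2G30620 rose by a log2 ratio of 2.97 and AT1G06760 rose 2.15-fold, while HTB2 had a log2 ratio of 0.98 and AT2G37470 of -0.17. The 1 that fell was the linker histone HIS1-3, at -2.58. The root hair markers EXPA18 and EXPA7 were at least 15.6-fold and at least 9.45-fold higher. GID1A, a gibberellin receptor, fell with a log2 ratio of -3.14, and SLY1 had a ratio of -0.34; of the 4 measured gibberellin genes 1 rose and 2 fell. Of the 3 measured storage lipid genes 2 fell; AIM1 had a log2 ratio of -1.42, which turned to 0.26 with poly-A control scaling, and isocitrate lyase (ICL) had -0.15 at signals of 5331 and 4792. PRL, a replication factor, was at least 3.19-fold higher. The reference genes had a median of -0.16 with 1 of 4 lower; their AT4G26410, PEX4 and AT2G28390 had log2 ratios of 0.10, -0.41 and 0.44.

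Among genes with a probe set paired with 1 name, above the floor on both arrays, the highest ratios besides that of RCA were those of PYK10, a β-glucosidase of endoplasmic reticulum bodies (log2 ratio 7.99), the jacalin-related lectin JAL34 (6.93), α-tubulin TUA6 (6.48), AT5G44020 (6.07), JAL33 (5.94), MSRB9 (5.84), AT2G10940 (5.76), AT1G74470 (5.73) and ZW9 (5.47). AT3G48140, AT1G09310, AT3G16370, NAI2 and AT5G64100 were at the floor in unimbibed seed and at least 219-, 184-, 144-, 106- and 98.2-fold higher after imbibition. Besides AT2G21490 and PAP85, given above, the lowest ratios were those of AT1G54870 (-9.18), AT5G45690 (-8.73), AT1G04560 (-8.48), AT3G05260 (-8.32), AT5G01300 (-8.00), AT3G53040 (-7.94), AT1G27990 (-7.90) and AT5G01670 (-7.68). Besides M10 and AT2G28490, AT1G14950, ATOEP16-2 and AT2G42560 were at the floor after imbibition and at least 445-, 433- and 412-fold lower.

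In all, 3669 probe sets were higher and 3425 lower, of 16246 measured on either array, and 1814 and 1952 of them had 1 gene name. The share of calls that were higher was 51.7% with the main scaling, 75.7% with signals as deposited, 76.7% with hybridisation controls set equal and 92.3% with poly-A controls set equal. Those scalings moved log2 ratios up by 0.71, 0.74 and 1.68 where both sides were above the floor, so directions are relative to the average transcript; the reference gene median was 0.55, 0.59 and 1.52 under them, and the gibberellin list median turned from -1.06 to 0.62 under the poly-A scaling. Probe sets of the same locus differed with an SD of 0.76 in this comparison.

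**Figure D1:**
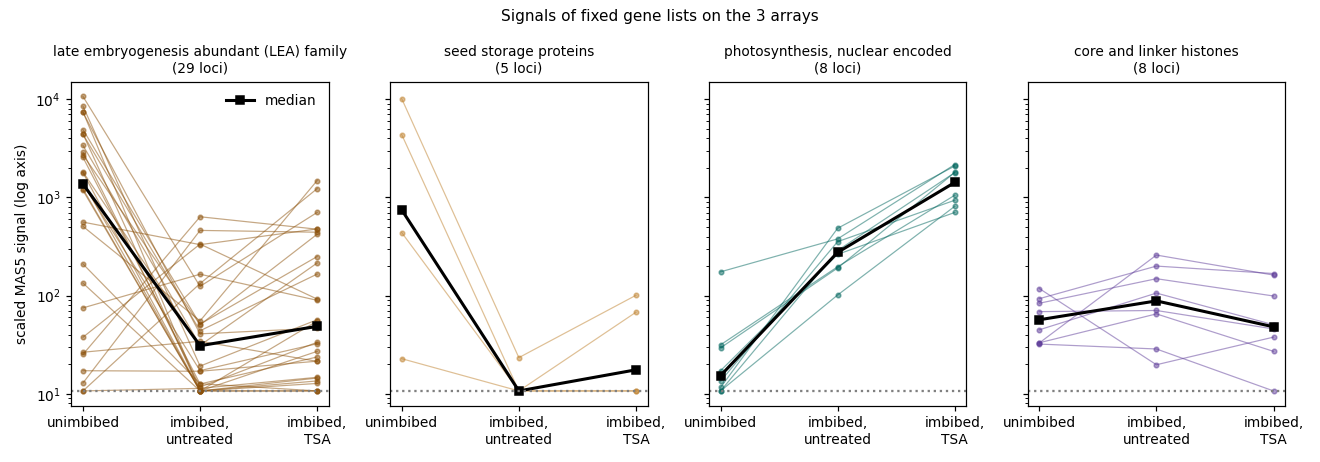
Scaled MAS5 signal (vertical log axis) on the unimbibed, untreated imbibed and TSA imbibed arrays for the measured loci of 4 gene lists. The histone panel holds H2B and linker histone genes only. Each thin line is 1 locus, the squares are list medians, and the dotted line is the floor of 10.7; all 8 photosynthesis loci were higher with TSA than without it.

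TSA-treated and untreated imbibed seed were compared because the series asks how germination differs with the inhibitor present. Photosynthesis transcripts were higher with TSA: all 8 measured nuclear members rose, with a median log2 ratio of 2.46 and a range of 1.40 to 3.23, above all random lists. LHCB4.2 went from 191.3 to 1795 (log2 ratio 3.23), PSAN from 101.6 to 811.2 (3.00), and LHCB4.1 from 378.3 to 2160 (2.51), while RCA rose 4.30-fold, from 485.3 to 2085. Among the plastid-encoded genes 43 of 67 rose and none of the 67 fell, with a median of 1.26, also above all random lists; petL and psbC had log2 ratios of 2.90 and 2.88, atpB 0.97 and clpP 0.09. The root hair markers EXPA7 and EXPA18 fell, with log2 ratios of -1.74 and -1.24, in the same comparison. Of the chlorophyll biosynthesis genes, CHLM rose 2.15-fold and PORB had a log2 ratio of -0.15.

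Of 27 measured LEA members, 11 rose with TSA and 1 fell, and the median of 0.66 lay above all random lists. Members with an untreated signal under 2 times the floor could not be called lower. AT3G02480 went from 55.4 to 1485 (log2 ratio 4.74), against 507.4 in unimbibed seed. COR47, a dehydrin that responds to cold, went from 133.1 to 1227 (log2 ratio 3.21). It was at the floor in unimbibed seed and at least 12.4-fold higher after imbibition without TSA. AT3G15670 went from 124.4 to 703.5 with TSA (5.66-fold) and the dehydrin AT2G21490 from 19.2 to 56.9 (log2 ratio 1.57). Of 3 measured storage protein transcripts 2 rose: PAP85 by a log2 ratio of 2.11, and AT2G28490, which was at least 6.32-fold higher. The oleosin AT3G01570 rose by a log2 ratio of 3.27 and was the 1 of 4 oil body members past 2-fold; AT2G25890 had 0.94. These storage and oil body signals stayed far below those of unimbibed seed, at 100.9 against 10078 for PAP85 and 303.0 against 5328 for AT3G01570. BZIP53, a regulator of maturation genes, rose by a log2 ratio of 1.36, and EEL had 0.20.

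The measured H2B and linker histones had a median of -0.65, at the percentile 2.79 of random lists, with 3 of 8 lower and 0 higher. HTB2 fell with a log2 ratio of -1.27, AT2G37470 was at least 2.67-fold lower, and the linker histones AT1G06760 and AT2G30620 had -0.25 and -0.68. The linker histone HIS1-3, the 1 of 8 above 0, had 0.93. In the cell wall expansion list 4 of 9 rose and 1 fell, with a median of 0.51 at the percentile 94.6. EXPB1 was at least 7.78-fold higher, EXPA8 rose by a log2 ratio of 2.36 and XTH16 by 1.16, and XTH19 had 0.13. GSTU25, a glutathione S-transferase, rose by a log2 ratio of 2.82 and dihydroflavonol reductase (DFR) by 1.71, and the anthocyanin glycosyltransferase UF3GT was at least 2.36-fold higher. Of 4 small heat shock proteins 1 rose: ATHSP22.0 was at least 3.96-fold higher, while AT5G51440 had a log2 ratio of -0.89 and AT1G53540 of -0.22.

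No measured member passed 2-fold in the remaining lists. The log2 ratios were -0.32 for the deacetylase HDA15, -0.84 for PRL, -0.09 for the defence regulator WRKY53, -0.67 for GID1A, 0.42 for SLY1, -0.19 for ICL and 0.17 for AIM1. The reference genes AT4G26410, PEX4 and AT2G28390 had -0.71, 0.64 and -0.66, with a list median of -0.26. The seed coat, endosperm and meristem lists each had 1 named member, which was not above the floor in these imbibed seeds, and the aquaporin, histone acetyltransferase, embryo programme repressor and abscisic acid lists had 0 named members.

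Among genes with a probe set paired with 1 name, above the floor on both arrays, and besides AT3G02480 and AT3G01570 given above, the highest ratios were those of AT2G37870 (log2 ratio 5.45), AT5G44440 (4.82), AT5G48490 (4.28), AT4G33550 (3.95), AT3G22620 (3.88), hydroxypyruvate reductase HPR of photorespiration (3.58), the chitinase CHI (3.41) and AT1G04560 (3.36). AT5G04120, AT3G53980, ECS1, AT4G38080 and AT3G06070 were at the floor without TSA and at least 41.1-, 29.6-, 28.3-, 28.2- and 21.0-fold higher with it. The lowest were AT5G01870 (-3.64), AT4G33560 (-3.45), AT4G39675 (-3.15), AT3G16310 (-3.01), AT4G12600 (-3.01), AT4G34290 (-2.79), AT4G02930 (-2.77), DAL1 (-2.69), AT2G20450 (-2.63) and AT2G44640 (-2.61). AT4G16240, AT5G39850, scpl44, AT2G18330 and AT5G49560 were at the floor with TSA and at least 7.09-, 6.72-, 6.36-, 5.61- and 5.51-fold lower.

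In all, 1639 probe sets were higher and 1493 lower with TSA, of 15700 measured on either array, and 356 and 149 passed 4-fold. The upper noise estimate takes as noise the median absolute deviation of the TSA ratios of probe sets above the floor on both arrays. Simulations with that noise and no TSA effect made 1120 higher and 1117 lower calls on average, so many calls near 2-fold are within that estimate. The share of calls that were higher was 52.3% with the main scaling and 54.2% as deposited, but 46.5% with 75th percentile scaling, 46.3% with hybridisation controls set equal and 22.4% with poly-A controls set equal, so neither direction held the majority under every scaling. The poly-A scaling moved log2 ratios by -0.43 where both sides were above the floor. The log2 signals of probe sets above the floor on both arrays correlated with r = 0.83 across probe sets, which are not independent replicates, against 0.45 for imbibed and unimbibed seed.

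TSA-treated seed was also compared with unimbibed seed. LEA transcripts were lower, with a median log2 ratio of -4.29 and 19 of 29 lower, as were storage proteins (-6.00, 5 of 5) and small heat shock proteins (-3.81, 4 of 6). Photosynthesis transcripts were higher, with a median of 6.02 and 8 of 8 higher, as were cell wall expansion (4.18, 9 of 9) and plastid-encoded genes (2.39, 55 of 66). The histone median was -0.06, and above 0 with signals as deposited and with either control scaling. In all, 3808 probe sets were higher and 3759 lower. The share of calls that were higher was 50.3%, against 75.3% as deposited, 73.1% with hybridisation controls and 86.7% with poly-A controls set equal.

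The calls of the first 2 comparisons were then overlapped, to ask how far TSA-treated seed lay on the unimbibed side of untreated seed. Of the 302 probe sets that fell at least 16-fold on imbibition, 104 were higher and 5 lower with TSA, with a median log2 ratio of 0.58, and their median against unimbibed seed was still -4.91. A set chosen for low untreated signal leans to higher ratios by its choice: in simulations with no TSA effect, such sets had 20.5 higher and 8.70 lower on average, at most 34 higher, and a median of at most 0.08. The noise in all these simulations came from probe sets above the floor on both imbibed arrays. It may be too small for dim probe sets and for the unimbibed array, so the simulated maxima may be too low. Of the 318 that rose at least 16-fold, 55 were higher and 82 lower with TSA, against simulated means of 15.1 and 42.3 and maxima of 25 and 60. Over all calls, 420 probe sets fell on imbibition and were higher with TSA, against 327 for independent lists and at most 375 in simulations with no TSA effect. The simulations made fewer TSA calls, and as a share of the TSA-higher calls the overlap was 25.6%, below the simulated 29.5% (range 26.1 to 33.1%). A total of 715 rose on imbibition and were lower with TSA (319 if independent, at most 630 simulated), which is 47.9% of the TSA-lower calls against a simulated 50.8%. Both counts were above the highest simulated ones and neither share was above the simulated mean, and a share also falls when other TSA calls are more numerous. A further 414 rose and were higher (351 if independent, at most 207 simulated), 25.3% of the TSA-higher calls against a simulated 15.6%, and 109 fell and were lower (298 if independent, at most 133 simulated). Both ratios hold the untreated array, which cannot be split, so part of any excess may come from that array. The counts of 420 and 715 are for the main processing. Both changed by over 1.5-fold with poly-A control scaling, with the floor at the 25th percentile and without a floor. The count of 420 also did so with the floor at the 60th percentile, and that of 715 with hybridisation control scaling.

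**Figure D2:**
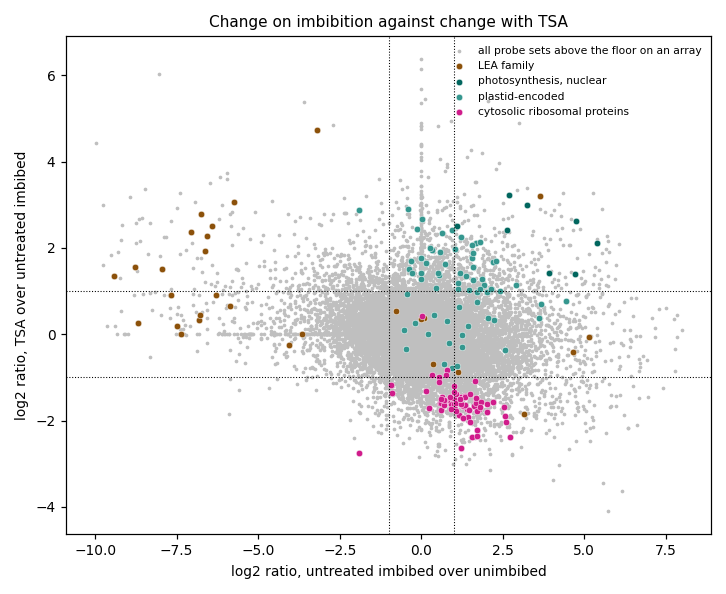
Log2 ratio of untreated imbibed over unimbibed seed (horizontal) against log2 ratio of TSA over untreated imbibed seed (vertical) for every probe set above the floor on an array, with loci of 4 gene groups in colour and dotted lines at 2-fold. LEA loci lie mostly to the left of the centre, and photosynthesis loci lie above the upper 2-fold line; the ribosomal protein loci were chosen after their values were seen.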

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

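All tests in this part were chosen after the results they measure had been seen. With 1 array per state, an effect of TSA is untested for every pattern below, as is any difference between batches of seed.

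The poly-A control transcripts, which enter the comparisons only as an alternative scaling, differed between the arrays. As deposited, their signals were higher on the unimbibed array than on the untreated imbibed array by a mean log2 ratio of 0.97 (1.96-fold; SD 0.25 over 27 probe sets), and higher on the TSA array than on the untreated one by 0.46 (1.38-fold; SD 0.21).

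LEA transcripts that fell on imbibition were higher with TSA, with a median log2 ratio of 1.43 over 18 measured members, of which 10 rose and 0 fell. Over all 20 that fell the median was 1.13, and from 0.54 (floor at the 60th percentile) to 1.71 (no floor) over the alternatives. A member with an untreated signal under 2 times the floor could not be called lower. Several were that dim, among them AT3G53040 at 11.8, so the count of 0 says little. Array scaling moves loci above the floor alike and choosing fallen loci favours higher ratios. This median still exceeded that of random lists of other fallen loci with like untreated signal by 1.14 and lay above their range, 0.03 to 0.64. Those other loci had fallen at least 2-fold and were not matched on the depth of the fall. Probe sets that fell at least 16-fold had a median of 0.58 as a whole, so a rise particular to LEA was not shown. RNA of unimbibed-like seeds in the TSA sample would add 1 common share of the unimbibed signals. The best share, 0.871%, left a residual SD of 1.65, above the bound of 0.95 from the noise estimate. Without AT3G02480, the member farthest from that share, the residual SD was 1.24. The bound came from probe sets above the floor on both imbibed arrays. Several of the LEA members were at the floor untreated, so the bound may be too small for them. A further count took probe sets bright in unimbibed seed with a signal of at most 50 in untreated seed. The percentage of them that gained under 20% of the median LEA gain went from 10 to 26.9 with the signal limit, which decided nothing. Their median gain was 0.41 to 0.68% of the unimbibed signal, so such transcripts also gained as a group. The LEA median gain was 1.05%, but the LEA members were not held to these signal limits. LEA probe sets within the limits were also counted in the group, so these medians do not show that LEA gained more. Unimbibed-like seeds as a part of the difference, seeds held at a later stage than unimbibed, and an effect of TSA on these genes stay open and may act together.

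Photosynthesis transcripts were higher with TSA. Array scaling is argued against by a list median 2.495 above that of all measured loci. The same list rose on imbibition, so a uniform delay of germination would lower it if these transcripts have no peak before day 3. The list median of 2.46 goes against a delay only in that case, since no time in between was measured. A smaller share of root RNA could raise all shoot transcripts by a common factor. PORB had -0.15, CHLM rose 2.15-fold, and plastid genes for ribosomal proteins and RNA polymerase had a median of 0.31, which goes against such a factor if they are shoot transcripts, but no table here shows where in the seed they are expressed. The SD of the members was 0.67, within the bound of 1.07. The root hair markers had a median of -1.49, over only 2 of 6 listed markers. A smaller root share and an effect of TSA in the shoot thus cannot be told apart with 8 members and whole seeds.

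Cytosolic ribosomal protein transcripts were lower with TSA, with a median log2 ratio of -1.60 over 69 loci. In the same comparison the 2 measured root hair markers had a median of -1.49. The deposited signal of the 25S ribosomal RNA probe set was 1614.3 without and 898.4 with TSA, against 426.9 in unimbibed seed. That signal was not scaled as the ratios were, and its relation to the ribosomal protein transcripts was not tested. The ribosomal protein median lay -1.57 from that of all measured loci, outside the range of random lists, which argues against array scaling. A bias by gene length is argued against by 91 other loci of like length and at least like signal, whose median was -0.11 (95% bootstrap interval -0.39 to 0.16). The length used was that of the gene and not of the transcript, so a bias by transcript length was not tested. A delay of germination could leave these transcripts nearer their unimbibed level: the TSA over unimbibed median was -0.41 and went from -0.41 to 0.80 over 6 scalings, inside the span that a delay allows under 3 of them, so it cannot be told apart from an effect of TSA.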

How the results depend on the processing

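Poly-A control scaling was chosen after seeing the data; the other alternatives were fixed in advance. With 1 array per state no paired or left-out fit exists, and the floor limits every ratio that has a dim side. In the TSA comparison 5 list medians kept their direction under every alternative, with photosynthesis from 2.03 to 2.72, LEA from 0.36 to 0.91, plastid-encoded genes from 0.83 to 1.29, histones from -1.08 to -0.60 and cell wall expansion from 0.08 to 0.61. Poly-A control scaling turned the medians of the storage lipid list (3 measured genes) from 0.11 to -0.32 and of the gibberellin list (4) from 0.16 to -0.27. Of 701 single-gene values in that comparison 669 stayed within 1.5-fold and 32 moved further; for imbibition 446 of 702 stayed, 255 moved, and 1, AIM1, was past 2-fold and changed sign. Counting values within 2-fold as well, 29 changed sign for imbibition, 9 of them with poly-A control scaling, and 6 in the TSA comparison. The imbibition values that turned positive with poly-A control scaling included those of BZIP53 (1.01), HDA15 (1.36), SLY1 (1.34), ICL (1.53), PEX4 (1.27), clpP (1.14) and petL (1.28). Fewer or more calls under another floor or threshold follow from their construction, as do shifts under another scaling; the cause of other moves was not tested.

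As deposited, 5670 probe sets were higher and 1820 lower after imbibition, and 1864 lower in TSA-treated than unimbibed seed. The imbibition medians were -5.60 for LEA, -3.003 for small heat shock proteins, 4.18 for cell wall expansion and 1.61 for histones; against unimbibed seed, the TSA medians were -3.55 for LEA, -5.26 for storage, -3.16 for small heat shock proteins, 0.68 for histones and 3.05 for plastid genes. With quantile normalization LEA had -5.59 and -3.55 in these comparisons, and storage -5.16 in the latter.

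With hybridisation control scaling, 5837 were higher and 1775 lower after imbibition, 1998 lower in TSA-treated than unimbibed seed, and 1241 higher after imbibition and lower with TSA. The imbibition medians were -5.56 for LEA, -2.99 for small heat shock proteins, 4.23 for cell wall expansion and 1.65 for histones; TSA over unimbibed medians were -3.62 for LEA, -5.33 for storage and 0.61 for histones.

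With poly-A control scaling, 9789 were higher and 813 lower after imbibition, 3921 lower with TSA than without, and 7027 higher and 1075 lower in TSA-treated than unimbibed seed. The overlap of fallen and TSA-higher probe sets was 165, and of risen and TSA-lower 3340. Imbibition medians were -4.41 for LEA, -5.19 for storage, -2.15 for small heat shock proteins, 4.88 for photosynthesis, 4.70 for cell wall expansion, 2.58 for histones and 2.52 for plastid genes, and AIM1 turned to 0.26. TSA over unimbibed medians were -3.04 for LEA, -4.75 for storage, -2.66 for small heat shock proteins, 6.66 for photosynthesis, 1.19 for histones and 3.55 for plastid genes.

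With the floor at the 25th percentile, 2475 were lower with TSA, and the overlaps were 781 (fallen, TSA higher) and 1085 (risen, TSA lower); imbibition medians were -7.25 for storage and 4.57 for cell wall expansion, which had 5.31 for TSA over unimbibed. With the floor at the 60th percentile, 1070 were higher and 954 lower with TSA, with overlaps of 242 (fallen, TSA higher) and 267 (risen, TSA higher). Storage then had -5.04 for imbibition and -5.04 for TSA over unimbibed, small heat shock proteins -2.81 and -3.14, and TSA over unimbibed medians were 5.27 for photosynthesis and 3.10 for cell wall expansion.

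Without a floor, 6154 were higher and 5253 lower after imbibition, 3363 and 3439 with TSA, and 6160 and 5768 in TSA-treated over unimbibed seed, with overlaps of 1346 (fallen, TSA higher), 1446 (risen, TSA lower) and 720 (risen, TSA higher). Imbibition medians were -5.35 for LEA, -8.33 for storage, 4.24 for photosynthesis and 4.72 for cell wall expansion, which had 6.51 for TSA over unimbibed. At 4-fold, 1588 were higher and 1288 lower after imbibition, 356 and 149 with TSA, and 1806 and 1342 in TSA-treated over unimbibed seed. Over all LEA members, measured or not, the imbibition median was -4.89.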

Other observations

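The gene groups in this part were chosen after their values had been seen. Of 69 measured cytosolic ribosomal protein loci, 43 rose and 1 fell on imbibition, with a median log2 ratio of 1.19. With TSA 64 of the 69 fell and 0 rose, with a median of -1.60, below all random lists, and from -2.03 to -1.57 over the alternatives. The ribosomal protein genes AT5G39850 and AT2G20450 were among the named genes that were lower with TSA.

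Values of plastid genes are given by class, with no test between classes. With TSA, 33 of 41 measured plastid genes for photosynthesis rose, with a median log2 ratio of 1.62, and 4 of 19 for ribosomal proteins and RNA polymerase, with a median of 0.31 that turned to -0.12 with poly-A control scaling. The photosystem I genes (psa) had a median of 2.41, with 5 of 5 higher, and the RNA polymerase genes (rpo) -0.47, with 0 of 4 higher. On imbibition the medians were 0.94 for the photosynthesis class (0.69 to 2.18 over the alternatives) and 1.57 for the ribosomal protein and RNA polymerase class (1.55 to 3.25). Mitochondrial genes had a median of -1.43 on imbibition, with 6 of 11 lower, and from -1.65 to -0.29 over the alternatives. With TSA their median was -0.22, with 0 of 10 past 2-fold.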
